A study of Caenorhabditis elegans with 4 samples.

How the data were processed

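Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans hermaphrodites at the L4 stage, the last larval stage before adulthood. The strain carries a transgene in which FKH-10, a forkhead-family transcription factor, is fused to GFP, together with an unc-119 marker. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, and the tagged protein was collected with anti-GFP antibodies. A portion of each extract (10%) was set aside before the immunoprecipitation as input DNA. The series has 4 samples in 2 groups, 2 ChIP libraries and 2 input libraries, each numbered 1 and 2 in the labels. The labels do not say whether the replicates came from separate cultures, so every comparison between them measures only the spread between these 2 samples, which may be technical.

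The values analysed were 3 peak lists, 1 for each ChIP replicate and 1 for the whole series. Per the file headers, coordinates are on WormBase build WS220, and the source column names PeakSeq as the caller. The version of PeakSeq, its threshold, the aligner, and how the input libraries were used are not given in the sources used here. It is likewise not given whether the series-level list was called on pooled reads. Each peak has a first base, a last base, a number in its name and 1 deposited score, which has the properties of an adjusted p-value (q-value). No deposited score is above 0.000997. The score multiplied by the peak's number never fell as the number rose in any of the 3 lists (relative tolerance 1e-09), as Benjamini-Hochberg q-values without a running minimum would behave. In each list 2 peaks have a q-value of exactly 0. The smallest q-value was taken as the strongest peak, with ties broken by the peak's number. The files give no read counts, so sequencing depth is unknown, and the input libraries' own values were not analysed here. Because a q-value depends on depth, peaks were ranked by it within a list only, and its size was compared between lists in 1 place, the Pearson correlation across shared peaks.

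Replicates were compared by overlap. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The overlap expected by chance came from 10000 random circular shifts of the other list within each chromosome, which keep peak widths and spacing, and the resulting p is one-sided with a smallest possible value of 0.0001. Exact Clopper-Pearson 95% intervals are given for shares of peaks. They treat peaks as independent and cover counting error only. The relation of peak strength to overlap was tested by permuting which peaks overlap (100000 resamples, two-sided). Spearman's rho and Pearson's r of peak strength were computed across shared peaks with 100000 permutations. These correlations are across peaks of 1 pair of libraries, and peaks are not independent replicates.

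For the distribution over chromosomes, peaks within 1 kb of each other were first merged into clusters. Chromosome lengths of WS220 were not used here; each chromosome's span was taken from the first to the last base covered by any of the 3 lists. Clusters on X against autosomes, and in the central 33.3% of each autosome's span against the flanking parts, were tested with exact two-sided binomial tests, Benjamini-Hochberg adjusted over 6 tests (2 questions in 3 lists). The overlap count, the chance level and the X test were tested on simulated lists of about the length of the real ones. Their peaks were drawn evenly and independently within each chromosome, without the widest peaks, so they had no blocks and no denser centres. The simulations therefore do not show the error rate for peaks that crowd together. Of planted shared peaks, which were moved only a short distance, 99.6% were found. Of 400 pairs of unrelated lists, 5% gave p at most 0.05. A planted X-to-autosome ratio of 1.5 was recovered as 1.47 on average over 100 lists, and was past the threshold in 100% of them.

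The named peaks follow a rule set before the data were examined: the 8 strongest series-level peaks that overlap both replicate lists, and the strongest peak of each replicate list that does not overlap the other. The blocks of adjoining peaks were defined after the data were seen, as chains of series-level peaks with gaps of at most 5 kb whose peaks cover at least 10 kb. Alternatives set beforehand were stricter overlap rules, the stronger 50% of each list, lists of equal length, merged peaks, uniform placement, other cluster distances and each replicate's own list. The values without chromosome I and without the blocks were chosen after seeing the data. Planned comparisons of peaks with gene starts, with 24 gene lists and with the forkhead motif were not run, because the gene table used here is on another assembly (WBcel235) and no genome sequence of WS220 was used. Peaks at fkh-10 and at unc-119, which the rule would have named first, were not assigned for the same reason. Peaks are therefore given by position, without gene names, and no statement is made on whether they are exonic, intronic or intergenic. The WBcel235 table served only to place fkh-10 in the gene order of its chromosome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.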

Results

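Peaks of anti-GFP ChIP-seq from L4 hermaphrodites of the strain labelled as carrying FKH-10::GFP were listed for 2 replicates and, in 1 further list, for the series as a whole. The question addressed by the design is where in the genome the tagged factor is found. The list of replicate 1 held 1169 peaks and that of replicate 2 held 2468, a 2.11-fold difference (mean 1818.5 ± 919 SD, n = 2). The series-level list held 3792. Median peak widths were alike, at 390 bp in replicate 1, 374 bp in replicate 2 and 376 bp in the series-level list. Peaks covered 594 kb in replicate 1, 1118 kb in replicate 2 and 1732 kb in the series-level list. The depth behind each list is unknown, so the difference in list length could not be set against the number of reads.

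The strongest peaks lay on chromosomes I, X and IV. The first and second ranks in all 3 lists were adjoining peaks near the right end of chromosome I. The longer spanned positions 14719039 to 14750686 (31648 bp) and the shorter positions 14751201 to 14757035 (5835 bp). Both had a q-value given as 0 in every list, and their widths were nearly equal in the replicates, at 31639 and 31569 bp for the longer peak and 5779 and 5683 bp for the shorter. The next 4 series-level peaks all lay within 36.7 kb on the X chromosome. They were X 16350266 to 16359590 (q = 4.10e-243), X 16364253 to 16370520 (q = 1.55e-190), X 16343266 to 16347515 (q = 5.11e-150) and X 16374670 to 16379949 (q = 1.64e-119). In the replicate lists most of these regions were split into shorter peaks; the exception was X 16343266, which was a single peak of 4231 bp in replicate 1. The X 16350266 region, for example, held 5 peaks in replicate 1 and 4 in replicate 2.

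In both replicates the third rank was I 15063982 to 15067630 (replicate 1 coordinates, q = 2.24e-86 and 2.41e-62), which is absent from the series-level list. In replicate 2 it ended at 15067634, the last base of the chromosome I peak span. Whether it marks FKH-10 binding was not tested. Among series-level peaks found in both replicates, the seventh and eighth by series-level rank were much shorter than the first 6. The peak at IV 14032298 to 14034701 was 2404 bp wide and ranked 10 in replicate 1 (q = 2.51e-28) and 6 in replicate 2 (q = 2.72e-47). The peak at X 14525299 to 14526538 was 1240 bp wide and ranked 12 in replicate 1 (q = 7.46e-25) and 5 in replicate 2 (q = 2.43e-47). The strongest peak of replicate 1 with no counterpart in replicate 2 was II 1672057 to 1673571, at rank 77 (q = 8.08e-12), which is part of a longer chromosome II block nearly missing from replicate 2. The strongest peak of replicate 2 with no counterpart in replicate 1 was IV 5714961 to 5715618, at rank 141 (q = 2.28e-14). Both were covered by the series-level list, where the overlapping peaks ranked 182 and 555.

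The 6 strongest peaks of the series-level list belonged to 2 of 5 blocks in which adjoining series-level peaks covered at least 10 kb. The blocks were chosen after the data were seen, and the next longest chain of peaks covered 7093 bp. The chromosome I block (14719039 to 14759713) was 93.0% covered by series-level peaks, 92.6% covered in replicate 1 and 92.4% in replicate 2. The X block (16343266 to 16379949) was 90.8% covered by series-level peaks, 70.9% in replicate 1 and 73.6% in replicate 2. A pair of blocks lay on chromosome IV. That at 7027331 to 7063013 was 47.7% covered in the series-level list, 20.0% in replicate 1 and 17.3% in replicate 2. That at 9062752 to 9078892 was 69.4% covered in the series-level list, 37.9% in replicate 1 and 38.4% in replicate 2. The chromosome II block (1644473 to 1674211) was 67.2% covered in the series-level list and 42.8% in replicate 1, but 5.28% in replicate 2. Together the 5 blocks held 6.89% of all bases in series-level peaks.

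**Figure D1:**
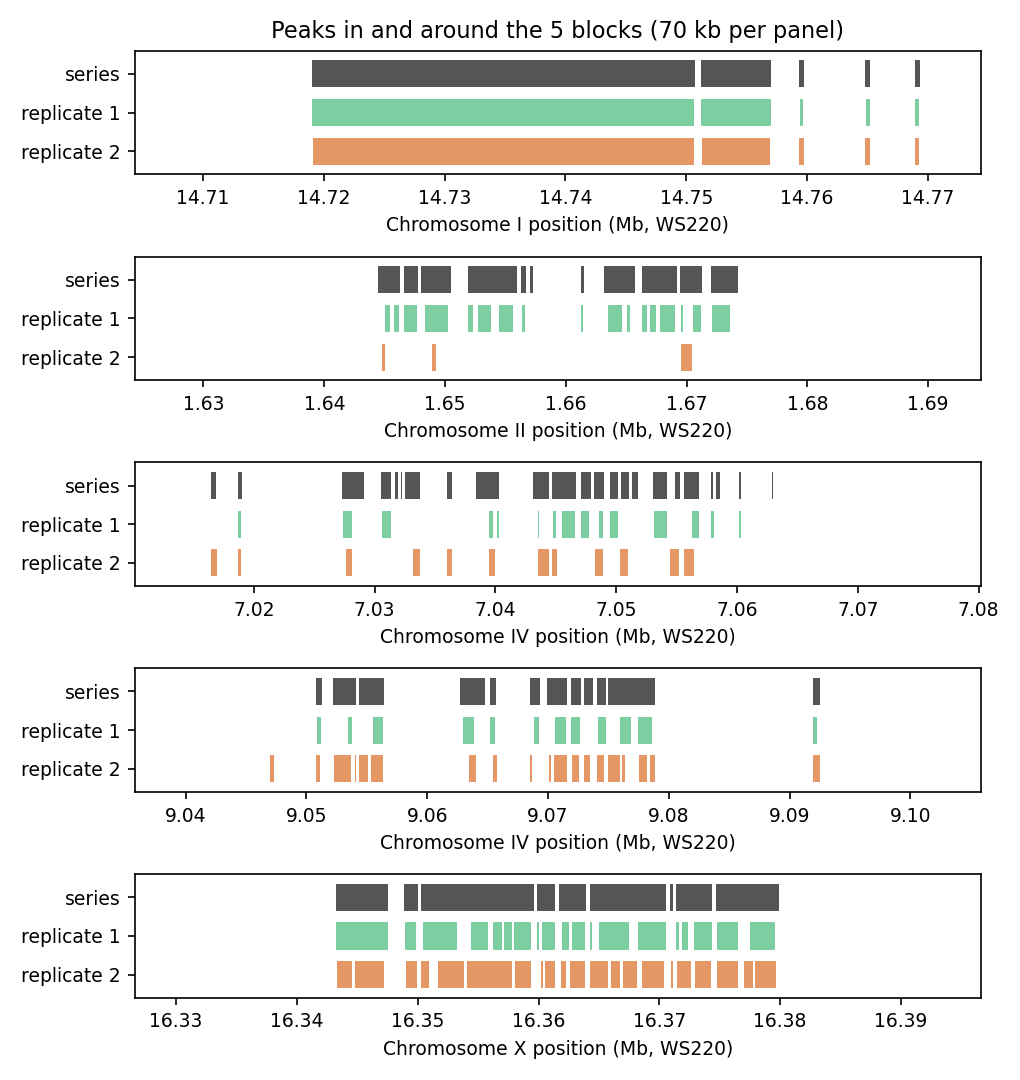
Peaks of the series-level list and of both ChIP replicates around each of the 5 blocks, with genomic position in Mb (WS220) on the horizontal axis and 1 row of bars per list; each bar is a peak drawn to scale. The chromosome I block is filled almost without a break in all 3 lists, whereas the chromosome II block holds 17 peaks in replicate 1 and 3 in replicate 2.

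Most peaks of the shorter list recurred in the longer one. Of the 1169 peaks of replicate 1, 1056 (90.3%, 95% interval 88.5 to 92.0) overlapped a peak of replicate 2, where circular shifts gave 2.51% on average and 15.9% at most. In the other direction, 1056 of 2468 peaks of replicate 2 (42.8%, interval 40.8 to 44.8) overlapped replicate 1, against 1.20% by chance. Both shares were above every shift (one-sided permutation p = 0.0001, the smallest these shifts can give). Some random shifts may have been too short to separate matching peaks, which can raise the highest shifted value. For replicate 1 peaks, uniform placement gave 3.93% at most over 1000 repeats. The lists differ in length, which limits the second share. When the 1169 strongest peaks of replicate 2 were set against the 1169 of replicate 1, 71.1% of replicate 1 and 70.9% of replicate 2 peaks were shared.

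Sharing followed peak strength in both lists. In replicate 1, 98.0% of the strongest quartile and 76.0% of the weakest overlapped replicate 2, a difference of 21.9 percentage points. In replicate 2 the share was 88.98% in the strongest quartile, 48.8% and 23.2% in the following ones and 10.2% in the weakest, a difference of 78.8 points. Overlapping peaks ranked higher than the others in each list (permutation p = 1e-05 for both, the smallest these resamples can give). Across the 1056 shared peaks, strength in the replicates was correlated, with Spearman's rho of 0.61 (permutation p = 1e-05) and, for −log10 q of the 1054 pairs with q above 0, Pearson's r of 0.72 (permutation p = 1e-05). Without the 2 most extreme peaks r was 0.71. All permutation p-values in this paragraph equal the smallest that the resamples can give. A Benjamini-Hochberg adjustment over them would leave them unchanged.

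The series-level list contained almost all peaks of both replicates and many more. It overlapped 1159 of 1169 replicate 1 peaks (99.1%) and 2394 of 2468 replicate 2 peaks, leaving 10 and 74 without a counterpart. Of its own 3792 peaks, 1033 (27.2%) overlapped both replicate lists, 1330 (35.1%) only replicate 2, 93 (2.45%) only replicate 1, and 1336 (35.2%, interval 33.7 to 36.8) neither. The share found in neither list rose from the strongest to the weakest peaks. Among the strongest 380 peaks (q up to 4.76e-16), 372 were in both lists and 0 in neither. Among the weakest 380 (q of 4.61e-04 and above), 0 were in both and 335 (88.2%) in neither. Restricted to the stronger 1896 peaks, 54.1% were in both lists and 5.49% in neither.

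**Figure D2:**
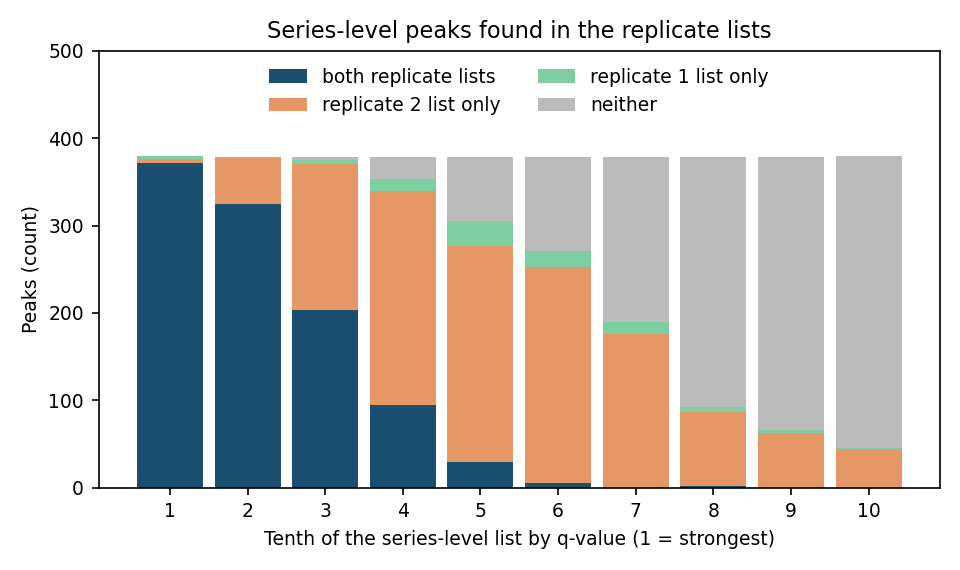
Number of series-level peaks (vertical axis) in 10 equal groups ordered by q-value from strongest (1) to weakest (10), coloured by whether they overlap both replicate lists, 1 of them, or neither. The strongest group has 372 of 380 peaks in both lists, and the weakest has 335 of 380 in neither.

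Peaks were denser on the X chromosome than on the autosomes and denser in the centres of the autosomes than toward their ends. After merging peaks within 1 kb, 743 of 3354 series-level clusters (22.2%, interval 20.8 to 23.6) lay on X, which made up 17.4% of the span. The density on X was 1.35 times that of the autosomes (exact binomial test, adjusted p = 3.23e-12). The ratio was 1.55 in replicate 1 (adjusted p = 1.72e-09, exact) and 1.38 in replicate 2 (adjusted p = 9.66e-10, exact). Among the 2611 autosomal clusters, 1154 (44.2%, interval 42.3 to 46.1) lay in the central 33.3% of the span, a density 1.58 times that of the flanking parts (exact binomial test, adjusted p = 6.97e-30). This ratio was 1.69 in replicate 1 (adjusted p = 3.17e-13, exact) and 1.61 in replicate 2 (adjusted p = 4.28e-22, exact). The central share was highest on chromosomes V (49.6%) and I (49.0%), followed by II (44.96%) and IV (41.6%), and lowest among the autosomes on III (36.9%, interval 32.9 to 41.1). On X, which was not part of this test, the central share was 31.2% (interval 27.9 to 34.7). The binomial tests treat clusters as independent and assume equal mappability along the span. They also ignore the spread between autosomes, whose series-level densities ran from 29.9 (V) to 45.8 (III) peaks per Mb, against 48.2 on X. The p-values for X therefore do not show that X stands apart from every autosome.

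By chromosome, the series-level list had 48.2 peaks per Mb on X, 45.8 on III, 40.6 on II, 35.1 on IV, 31.6 on I and 29.9 on V. X was also the densest chromosome in replicate 1 (17.1 peaks per Mb), but in replicate 2 chromosome III (33.2) stood slightly above X (32.8). Chromosome I stood lower in the replicates than in the series-level list. It held 12.6% of series-level peaks (interval 11.5 to 13.6) but 6.16% of replicate 1 peaks (interval 4.85 to 7.69) and 7.70% of replicate 2 peaks (interval 6.68 to 8.82). Its density relative to the other chromosomes together was 0.81 in the series-level list, 0.37 in replicate 1 and 0.47 in replicate 2. Because chromosome I counts among the autosomes, the X ratio was also taken without it, and was then 1.32 in the series-level list, 1.39 in replicate 1 and 1.26 in replicate 2 (exact binomial p = 1.32e-10, 7.53e-06 and 1.41e-05).

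**Figure D3:**
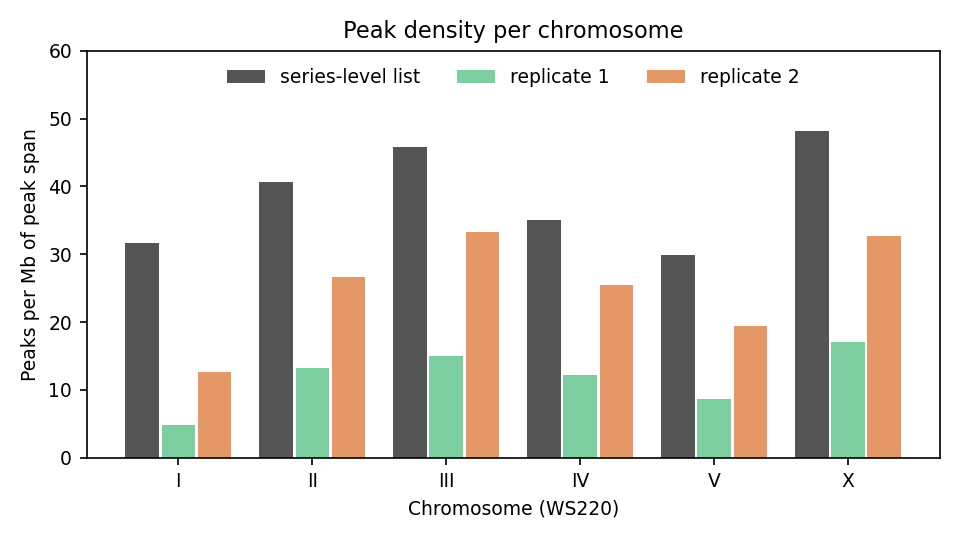
Peaks per Mb of each chromosome's peak span (vertical axis, from 0) on the 6 chromosomes, with 1 bar for each of the series-level list and the 2 replicate lists. X has the highest series-level density (48.2 per Mb), and chromosome I has the lowest density of both replicates (4.78 and 12.6 per Mb).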

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

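Most of what is reported held under the alternatives. Of 51 alternative values for 12 results, 42 of them set before the data were examined, 47 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. None of these 51 reversed, but by this rule widths and counts could not reverse. The shares behind the counts did move: 54.1% of the stronger 50% of series-level peaks were in both replicate lists, against 27.2% of all. The values without chromosome I and without the blocks were chosen after seeing the data, and none of them changed a call. Sharing between replicates stayed between 71.1% and 92.0% for replicate 1 and between 39.6% and 70.9% for replicate 2. Spearman's rho stayed between 0.58 and 0.65. Among these values the X ratio ranged from 1.30 to 1.59 and the central-to-flanking ratio from 1.46 to 1.76. In replicate 2 without chromosome I, which is not among the 51, the X ratio was lower, at 1.26. In the stronger 50% of each list, the median peak width was larger, at 465 bp in the series-level list, 491 bp in replicate 1 and 452 bp in replicate 2, against 376, 390 and 374 bp; the cause was not tested. The number of series-level peaks found in at least 1 replicate list, 2456, was 1126 to 2363 when only 1 replicate list was used; the low value comes from leaving out replicate 2, whose list is the longer. No paired analysis was possible because the results come from the peak lists of the ChIP libraries alone, and values of the input libraries were not analysed here. Comparisons with gene starts, gene lists and the forkhead motif, and their alternatives, were not run. The overlap of the replicates has no value with 1 replicate left out. Since read depth is unknown, it cannot be said whether a peak listed in 1 replicate alone is absent from the other or was below its detection limit.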

Other observations

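The tests in this part were chosen after the results were seen. Outside the blocks, series-level peaks were crowded in a few windows of 100 kb. The most crowded was I 7300001 to 7400000 with 19 peaks, followed by II 7900001 to 8000000 with 18. In 1000 random placements of the same number of peaks per chromosome, no window held more than 17, and these 2 windows exceeded that. Even placement ignores the higher density in the centres of the autosomes, where both windows lie. When each peak was instead moved at random by up to 1 Mb, the most crowded window held 13 peaks at the median and 19 at most over 1000 repeats (one-sided permutation p = 0.003 for the window with 19), so neither window exceeded the highest of these. Both kinds of placement moved peaks singly, although the 3792 series-level peaks formed 3354 clusters within 1 kb. Regions split into several peaks may therefore add to the crowding, which was not tested. In these 2 windows replicate 1 had 5 and 7 peaks, and replicate 2 had 11 and 13.

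The 5 blocks raise the question of what DNA or binding they represent. One candidate explanation is extra DNA of the tagged fkh-10 segment recovered with the transgene. For 4 of the 5 blocks the tables argue against this, since they lie on II, IV and X, and fkh-10 is on chromosome I. For the block on I, gene order argues against it too: 938 of 2877 coding genes of chromosome I (32.6%) lie to the right of fkh-10 in the WBcel235 table, but only 308 kb, or 2.05% of the peak span, lie to the right of the block. The block on II also differed between the libraries, with a replicate 2 to replicate 1 ratio of covered bases of 0.12, against 0.87 to 1.04 in the other blocks and 2.06 outside them (17 peaks in replicate 1 and 3 in replicate 2). This block was picked out after its values were seen and compares 1 library with 1, so whether it is present alike in both cannot be told. Mixed or mislabelled material, other long DNA segments in it, and broad binding all stay open, as untested, since neither reads nor input values were analysed here. Peaks in the blocks may therefore not be FKH-10 binding sites, and mixed or mislabelled material would put the same doubt on every peak of the 3 lists.

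Series-level peaks on chromosome I were missing from the replicate lists more often than those elsewhere. On I, 288 of 476 (60.5%, interval 56.0 to 64.9) overlapped neither list, against 28.7% to 35.2% on the other chromosomes. Within 10 strata of series-level q-value the odds ratio was 17.2, above the highest of 1000 rotations of the flags (3.24, one-sided permutation p by rotation = 0.001, the smallest these can give). Without strata the odds ratio of I was 3.32. In strata 1 and 2, the strongest, 0 peaks of any chromosome were in neither list, so I showed no deficit there. In strata 3 to 5, 56.8% of 162 peaks on I and 96.5% of 975 elsewhere were found. Weaker series-level q-values on I therefore do not account for the difference. The strata rest on the series-level call itself, however. If that call treated chromosome I differently, weaker binding there is not excluded. A scaling set per chromosome and moved by the very strong block on I might have this effect. The other chromosomes with blocks had stratified odds ratios of 0.78 (X), 0.67 (II) and 0.66 (IV). Those without a block had 0.51 (III) and 0.73 (V). All of these ratios set a chromosome against the rest with chromosome I included, whose high share pulls them down. They therefore cannot show that a chromosome has no excess of its own. Such a scaling cannot be told apart from other causes. The other blocks were weaker than that of I, and no signal outside peaks was analysed. A biological difference is not named by the design, so none was tested.

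Of the peaks shared by both replicates, 4 are absent from the series-level list. The strongest, I 15063982 to 15067630, was numbered 3 in both replicates (q = 2.24e-86 and 2.41e-62). The others in replicate 1 coordinates were III 931227 to 931827 (q = 2.79e-09 in replicate 1 and 6.54e-10 in replicate 2), III 1299607 to 1300474 (q = 4.86e-07 and 2.03e-07) and X 293241 to 293627 (q = 7.98e-07 and 3.55e-06). These 3 were numbered 144, 302 and 320 of 1169 in replicate 1 and 409, 768 and 1082 of 2468 in replicate 2. Removal after the series-level peaks were numbered is a candidate explanation that the numbering argues against. The series-level numbers run to 3803 with 11 missing, the lowest missing number is 2622, and replicate 1 peaks of like strength to these 4 had series-level numbers of at most 871. Removal of such sites before numbering, or a different input or read set for the series-level call, stays open and was not tested.

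Ends of shared peaks differed between the replicates by a median of 52 bp at the first base and 48 bp at the last. Only 9 of 1056 pairs had both ends within 5 bp. They included the chromosome I peak numbered 3 (15063982 to 15067630 and 15063984 to 15067634) and X 293241 to 293627 (replicate 1 coordinates). Both of these are among the shared peaks absent from the series-level list. Another was III 10907527 to 10908731, whose first bases coincided and whose last bases were 4 bp apart. Peaks under 50 bp numbered 74 in the series-level list, and 68 of them (91.9%) overlapped neither replicate list. All 74 had q of 9.58e-07 or above, and in the strength groups from that range down 19.5% to 88.2% of all peaks were in neither list, so peak width was not separated from strength.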
